A study of Phascolarctos cinereus with 3 samples.

How the data were processed

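Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on endometrium, the lining of the uterus, of the koala (Phascolarctos cinereus). The series holds 3 libraries: 1 made with a rabbit antibody raised against the CENP-A of the tammar wallaby (Macropus eugenii), 1 made with CREST serum, a human anti-centromere IgG, and 1 of input chromatin. Each immunoprecipitation used 10 µg of antibody and chromatin from 100000 cells, and each library was built from 1 ng of DNA, per the labels' protocols. The negative control antibodies gave no measurable DNA, per the same protocols, so no control library enters any comparison. The input library is not analysed here, and the number of reads behind each list is unknown.

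The deposited files are 2 peak lists, 1 per antibody, each with 3 columns that give the scaffold, the start and the end of a peak. The scaffold names carry the assembly name phaCin_unsw_v4.1. The submitters' processing notes name Trimmomatic 0.36, Bowtie2 and MACS2 2.0.10.20131216, a read trimmer, a read aligner and a peak caller, and the names of the deposited files mark the peaks as broad peaks. The parameters, the threshold, the treatment of reads that align to several places and the use of input as the background of the peak calls are not given in the sources used here. Each list belongs to 1 library, so the peaks were not pooled over replicates. The lists analysed here give no height, fold enrichment, p-value or q-value. How reads that fit several copies of a repeat were placed can move both the number and the width of peaks in repetitive sequence. The smallest gap between neighbouring peaks was 1014 bp in the CENP-A list and 1020 bp in the CREST list, so enrichment interrupted by less than about 1 kb appears as 1 peak.

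Positions were read as intervals that count from 0 and are printed counting from 1. A CENP-A and a CREST peak were taken as overlapping when they shared at least 1 bp. Random placements show what peaks of the same number and widths would give: in 10000 placements, the peaks of 1 list were put at random, without overlapping each other, on the scaffolds where that list has them, and the other list was held fixed. The lengths of the scaffolds were not used here. Each scaffold was taken to end at its last listed peak of either list, which is called its known extent and is a lower bound of its length. This makes random overlaps more frequent than on the full scaffolds. Peaks of both lists at most 10 kb apart were joined into domains, and a domain was counted when it held at least 1 peak of each antibody. Shares of peaks carry 95% Wilson intervals and medians carry 95% intervals from the binomial distribution of ranks. Both kinds of interval treat peaks as independent and cover counting error only, since there is 1 library per antibody. No test between the antibodies and no p-value was computed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used. The overlap and placement steps were run on simulated data. All 200 of 200 planted overlaps, made by widening CENP-A peaks at both sides, were recovered among 1681 CENP-A peaks. The 60 simulated lists placed the 570 CREST peaks of scaffolds with a known extent under 1 Mb by the same step. Of these lists, 0 exceeded all of their 200 random placements. Both runs check the code only, and do not show that random placement describes these data.

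The comparisons, the alternatives and the rule for the regions named were fixed before the data were examined. The rule took the 5 domains with the most bases in peaks of both lists and the 5 scaffolds with the most peaks of each list. It also took the 10 overlapping regions and the 5 peaks of each list without an overlap that ranked highest by fold enrichment. Since the lists hold no fold enrichment, these were ranked by width instead. This ranking, and the split of scaffolds by known extent (20 kb, 100 kb, 1 Mb and 10 Mb), were chosen after the data had been seen. The alternatives were a minimum width of 500 bp, an overlap of 50% of the shorter peak, a tolerance of 1 kb between peaks, and joining distances of 1 kb and 100 kb. Comparisons planned on fold enrichment, genes, sequence composition and the whole assembly were not made: no genome sequence of this assembly was used here, and the gene table at hand describes another assembly (phaCin_HiC), whose coordinates were not mixed with these.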

Results

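To locate centromeric chromatin in the koala genome, chromatin from endometrium was immunoprecipitated with 2 antibodies to centromere proteins. CENP-A is the variant of histone H3 that marks active centromeres. CREST serum, from people with an autoimmune disease, recognises several centromere proteins. The CENP-A list held 2412 peaks on 321 scaffolds and covered 2461074 bp. The CREST list held 758 peaks on 237 scaffolds and covered 1374503 bp. Each list came from 1 library, and the depth behind the peaks is unknown, so every difference below describes these libraries and has no replicate check.

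Over all scaffolds together, CENP-A peaks were more numerous and narrower than CREST peaks. The median width was 522.5 bp for CENP-A (95% interval 482 to 558 bp) and 1092 bp for CREST (1008 to 1187 bp). Peaks under 500 bp made up 49.0% of the CENP-A list and 24.9% of the CREST list. Part of this contrast lay in the scaffolds: those with a known extent of at least 1 Mb held 69.7% of CENP-A but 24.8% of CREST peaks. Within each kind of scaffold the shares under 500 bp were closer. They were 21.5% (CENP-A) and 16.7% (CREST) under 1 Mb, and 61.0% and 50% at 1 Mb or more. At the upper end the lists were alike in number, with 65 CENP-A and 53 CREST peaks of at least 5 kb. The widest CENP-A peak spanned 15067 bp and the widest CREST peak 13214 bp.

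The first comparison asked whether both antibodies marked the same chromatin. Of the CREST peaks, 567 of 758 (74.8%, Wilson interval 71.6 to 77.8%) overlapped a CENP-A peak. Of the CENP-A peaks, 541 of 2412 (22.4%, 20.8 to 24.1%) overlapped a CREST peak. The 2 lists shared 1172123 bp, which was 85.3% of the CREST bases and 47.6% of the CENP-A bases. Peaks of both antibodies were found on 212 scaffolds, CENP-A peaks without CREST peaks on 109, and CREST peaks without CENP-A peaks on 25. All of the 10000 random placements on the same scaffolds gave less overlap. Their highest values were 46.6% of CREST peaks, 14.6% of CENP-A peaks and 709433 bp shared. Of the 1871 CENP-A peaks without an overlap, 1309 lay on scaffolds with no CREST peak listed, where none was possible. Counting only scaffolds with peaks of both lists, chosen after the data had been seen, 49.0% of CENP-A and 82.5% of CREST peaks overlapped.

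Peaks that overlapped a peak of the other list were wider than those that did not. CENP-A peaks that overlapped a CREST peak had a median width of 1785 bp (1617 to 1974 bp), 4.65 times the 384 bp (366 to 407 bp) of the other CENP-A peaks. CREST peaks that overlapped a CENP-A peak had a median width of 1530 bp (1321 to 1761 bp), 3.07 times the 498 bp (393 to 620 bp) of the other CREST peaks. A wide peak has a greater chance of an overlap, so the widths of these classes are not independent of the overlap itself. Of the peaks without an overlap, 1309 of 1871 (CENP-A) and 71 of 191 (CREST) lay on scaffolds with no peak of the other list. The pooled ratios also mix kinds of scaffold. With a known extent under 1 Mb the ratio was 2.93 for CENP-A and 2.57 for CREST, and with at least 1 Mb 2.84 and 2.64. Where exactly 1 peak of each list overlapped, which was so for 477 pairs, the boundaries lay close together. The starts differed by a median of 34 bp and the ends by a median of 40 bp, and in 63.9% of these pairs both edges lay within 200 bp. Of all 582 overlapping pairs, 517 lay on scaffolds with a known extent under 1 Mb. There 124 CENP-A and 100 CREST peaks began within 1 kb of the scaffold start, where the sequence itself can set an edge in both lists. The edge differences were not split by scaffold, so they are not a measure of the antibodies alone. The CENP-A peak was the wider one in 73.2% of the 477 pairs, with a median width ratio of 1.03.

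**Figure D1:**
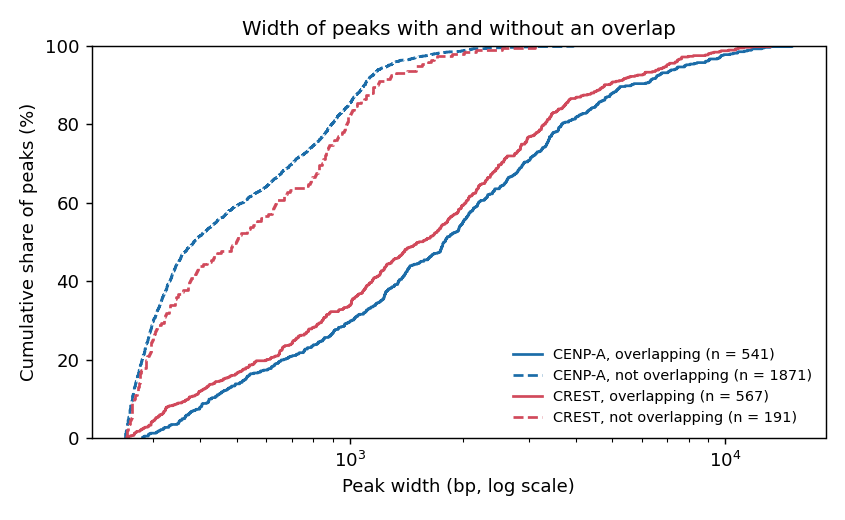
Cumulative share of peaks (%) against peak width (bp, log scale) for CENP-A (blue) and CREST (red) peaks that overlap a peak of the other list (solid) or do not (dashed). The solid curves lie to the right, with medians of 1785 bp and 1530 bp against 384 bp and 498 bp for the dashed ones.

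The widest regions covered by both antibodies lay on scaffolds of small known extent and had nearly the same limits in both lists. The widest was on scaf00730, where the CENP-A peak ran from position 239 to 13416 and the CREST peak from 218 to 13431, with 13178 bp in common. On scaf01611 the peaks ran from 317 to 12100 (CENP-A) and from 335 to 12089 (CREST), sharing 11755 bp. On scaf00865 they ran from 22863 to 34315 and from 22877 to 34050, sharing 11174 bp. The shared region on scaf00629 (32613 to 43281) measured 10669 bp and that on scaf01633 (536 to 11182) measured 10647 bp. The remaining members of the 10 widest, on scaf01582, scaf01674, scaf01565, scaf01034 and scaf00718, measured between 9000 bp and 9622 bp. Some of these limits lay near the scaffold start, as on scaf00730, scaf01611 and scaf01633, where the sequence itself limits peaks of both lists.

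The second comparison was between scaffolds, since peaks of both antibodies gathered on scaffolds of small known extent. The 244 scaffolds with a known extent under 1 Mb summed to 12.5 Mb, against 1110 Mb for the 102 scaffolds of at least 1 Mb. Peaks of either list covered 13.0% of the known extent on the former and 0.0936% on the latter. Part of this contrast is built in, since scaffolds without a peak are not counted and each known extent ends at its last peak. The scaffolds under 1 Mb held 88.9% of the CREST bases and 61.0% of the CENP-A bases. On them 88.2% of CREST peaks (503 of 570, Wilson interval 85.3 to 90.6%) and 65.5% of CENP-A peaks (479 of 731, 62.0 to 68.9%) overlapped a peak of the other list. On the scaffolds of at least 1 Mb these shares were 34.0% (64 of 188, 27.6 to 41.1%) and 3.69% (62 of 1681, 2.89 to 4.70%). Of those 1681 CENP-A peaks, 1151 lay on scaffolds for which no CREST peak was listed. Counting only scaffolds with peaks of both lists, 62 of 530 (11.7%, 9.23 to 14.7%) overlapped on scaffolds of at least 1 Mb and 479 of 573 (83.6%, 80.3 to 86.4%) on smaller ones. The share of CENP-A peaks with a CREST peak was lower in each larger class of extent, from 75.9% under 20 kb and 66.2% between 20 and 100 kb to 43.8% between 100 kb and 1 Mb, 8.39% between 1 and 10 Mb and 1.83% at 10 Mb or more. In each of the 5 classes and for both lists the observed share lay above the highest of 10000 random placements. On scaffolds under 1 Mb that highest value was 47.6% of CENP-A peaks and 61.8% of CREST peaks, so dense packing alone gave many overlaps there. On scaffolds of at least 1 Mb it was 0.297% and 4.26%. The difference between small and large scaffolds in the CENP-A share was 61.8 percentage points, against a median of 42.8 and a highest value of 46.5 points in random placements, and a median of 28.0 points when each scaffold was taken as 2 times its known extent. By width of the CENP-A peak the difference was 24.1 points under 350 bp, 40.4 points from 350 to 500 bp, 48.4 points from 500 to 1000 bp, 56.1 points from 1000 to 2000 bp and 19.1 points at 2000 bp or more. In this last class 230 of 248 (92.7%, Wilson interval 88.8 to 95.4%) overlapped a CREST peak on scaffolds under 1 Mb and 14 of 19 (73.7%, 51.2 to 88.2%) on longer ones. Random placements gave medians of 12.2, 16.9, 22.9, 39.8 and 74.2 points in the 5 classes of width.

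**Figure D2:**
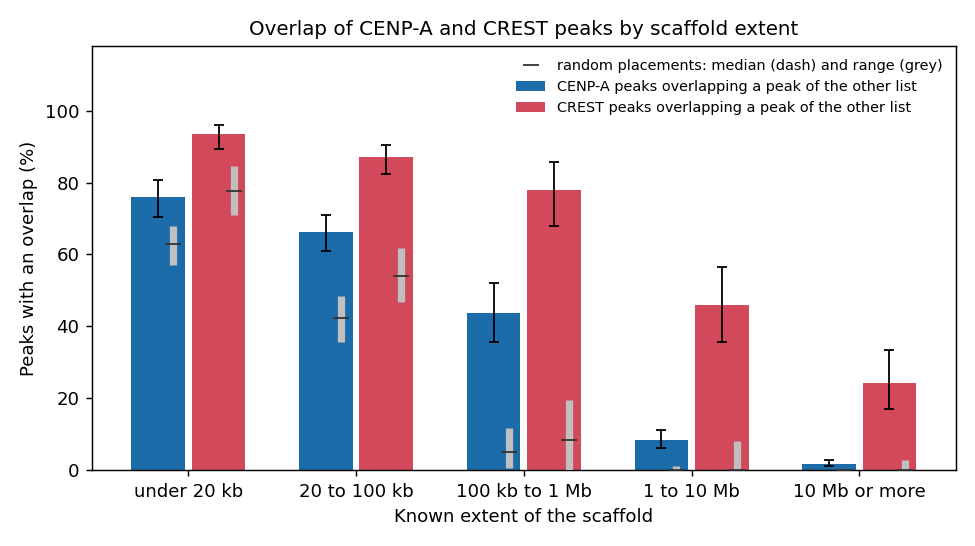
Share of CENP-A (blue) and CREST (red) peaks that overlap a peak of the other list (%), by known extent of the scaffold. Black bars are 95% Wilson intervals, and the dash and grey bar give the median and the range of 10000 random placements. The CENP-A share goes from 75.9% on scaffolds under 20 kb to 1.83% on those of 10 Mb or more.

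Joining peaks at most 10 kb apart gave 2069 domains, of which 253 held peaks of both antibodies. These 253 domains lay on 211 scaffolds, summed to 2701918 bp and had a median length of 8278 bp (95% interval 6507 to 10055 bp). They took in 612 CREST peaks (80.7%) and 626 CENP-A peaks (26.0%). Scaffolds with a known extent under 1 Mb held 208 of them, with 2423722 bp, and 77 of the 253 had at least 3 peaks of each antibody. Of the other domains, 1677 held CENP-A peaks alone, 1611 of them a single peak, and 139 held CREST peaks alone. All 181 scaffolds under 1 Mb with peaks of both lists held a domain of both antibodies. Random placement also put a median of 79.4% of CENP-A and 81.9% of CREST neighbours on scaffolds under 1 Mb within 10 kb. No random placement was set beside the domains, so their number and length there do not show more than scaffold size.

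The domain with the most bases in peaks of both lists lay on scaf00611, from position 284 to 58284. It held 12 CENP-A and 13 CREST peaks, and 31849 bp (54.9% of its length) were covered by both. The longest domain, on scaf00586 from 1792 to 65186, held 14 peaks of each antibody and 27934 bp (44.1%) in common. The domain on scaf00865 (1189 to 34315) was the most densely covered of these 5, with 74.8% of its 33127 bp in peaks of both lists. Those on scaf00718 (2243 to 43238) and scaf00730 (218 to 40682) had 24732 bp and 23410 bp in common. Within all 5 domains the peaks were separated by stretches called in neither list. All 5 ended at the end of the known extent, which is set by the last peak itself. On scaffolds of at least 1 Mb the domain with the most shared bases, chosen after the values were seen, was on scaf00255 (3672586 to 3699027), with 5 CENP-A and 4 CREST peaks and 14103 bp in common.

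**Figure D3:**
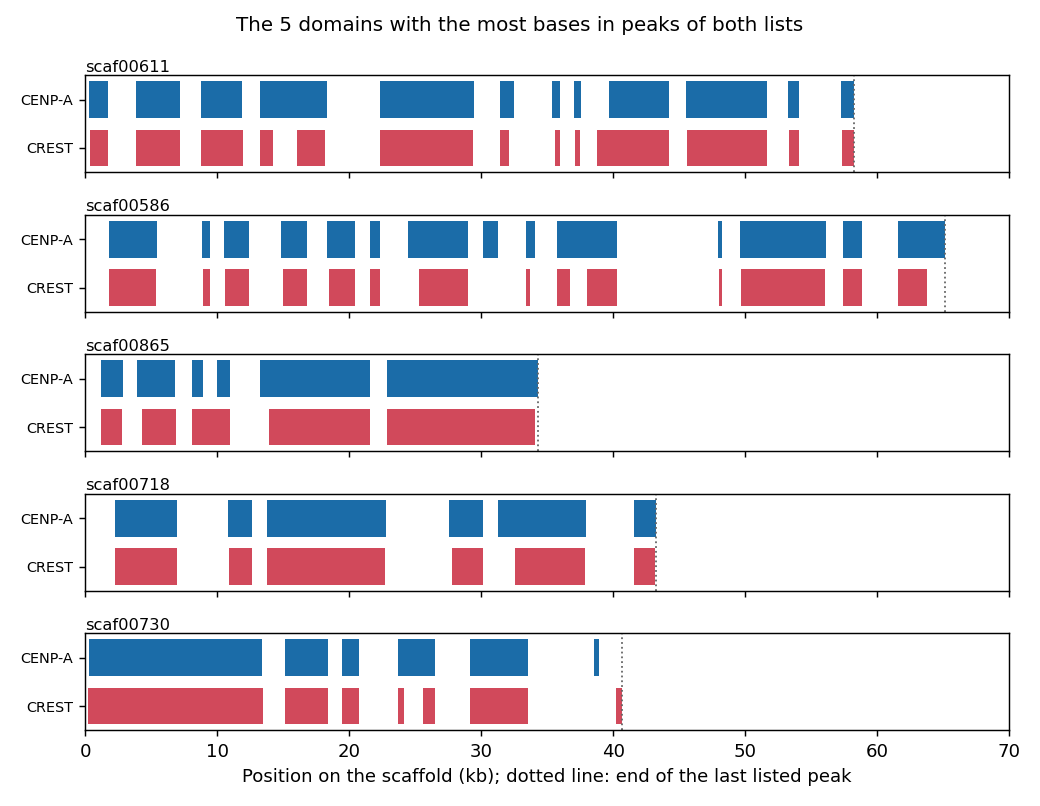
CENP-A (blue) and CREST (red) peaks in the 5 domains with the most bases covered by both lists, drawn to scale against position on the scaffold (kb). The dotted line is the end of the last listed peak, and the peaks of both lists cover largely the same segments, for example 31849 bp in common on scaf00611.

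Neighbouring peaks lay within 10 kb of each other in 68.7% of CREST pairs (358 of 521, Wilson interval 64.6 to 72.5%) and 22.7% of CENP-A pairs (475 of 2091, 21.0 to 24.6%). The highest random values were 62.6% and 21.9%. On scaffolds under 1 Mb the CENP-A value of 82.0% lay inside the random range of 75.6 to 83.8%, while the CREST value of 87.7% lay above its range of 77.6 to 86.1%. This CREST excess came from scaffolds of 100 kb to 1 Mb (39 of 65 pairs, against at most 41.5% at random), while the values lay inside the random ranges under 20 kb (99.1%) and from 20 to 100 kb (90.6%). On scaffolds of at least 1 Mb, 19.9% of CREST pairs and 4.03% of CENP-A pairs lay within 10 kb, against highest random values of 4.79% and 3.14%. For CENP-A this came from scaffolds of 1 to 10 Mb (8.67% against at most 5.15%), while the 2.32% on scaffolds of 10 Mb or more lay inside the random range of 0.516 to 3.44%.

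CENP-A peaks without an overlap differed between long and short scaffolds in width and in distance from CREST peaks. The distance is bounded by the scaffold, since those under 1 Mb had a median known extent of 15303.5 bp. No random placement was set beside the distances, so they do not show more than scaffold size. Of the 1871 CENP-A peaks without an overlap, 59.2% were under 500 bp wide, 1309 lay on scaffolds with no CREST peak, and 84 (4.49%) lay within 10 kb of a CREST peak. Most of them (1619) were on scaffolds of at least 1 Mb, with 62.3% under 500 bp and 1.05% within 10 kb of a CREST peak. On scaffolds under 1 Mb, 39.7% of the 252 such peaks were under 500 bp and 26.6% lay within 10 kb of a CREST peak. These shares include peaks on scaffolds with no CREST peak, 1151 of the 1619 and 158 of the 252. The widest of the 1871 were 2 peaks of 3939 bp each, on scaf01579 (9699 to 13637) and scaf01792 (653 to 4591), followed by peaks of 3771 bp on scaf00659, 3115 bp on scaf00459 and 2990 bp on scaf00164. None of these 5 scaffolds held a CREST peak. Of the 191 CREST peaks without an overlap, 42 (22.0%) lay within 10 kb of a CENP-A peak and 71 on scaffolds with no CENP-A peak. The widest was 3113 bp, on scaf00822 (594 to 3706), where another of 2171 bp was the third in rank and no CENP-A peak was listed. The others of the widest 5 were 2542 bp on scaf00692, 2012 bp on scaf00627 and 1869 bp on scaf00170, and lay between 12593 bp and 18630 bp from the nearest CENP-A peak.

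The scaffolds with the most peaks differed between the antibodies. CENP-A peaks were most numerous on scaf00001 (71 peaks), scaf00003 (54), scaf00007 (51), scaf00005 (50) and scaf00008 (48), whose known extents were 27.1 to 40.4 Mb. The CENP-A density on these 5 was between 1.40 and 1.77 peaks per Mb. Scaf00001 held 9 CREST peaks, 2 of which overlapped a CENP-A peak, and the other 4 held 0. CREST peaks were most numerous on scaf00385 (17 peaks), scaf00036 (15), scaf00586 (14), scaf00002 (13) and scaf00611 (13). On scaf00385, scaf00586 and scaf00611, with known extents of 910662, 65186 and 58284 bp, 14, 14 and 13 of the CREST peaks overlapped CENP-A peaks. On scaf00036, with a known extent of 18.1 Mb, 11 of the 15 did so. Scaf00002 had a known extent of 36.9 Mb and no CENP-A peak. Of scaffold numbers 1 to 100, 39 carried CENP-A peaks, with 8 to 71 each, and 61 carried none. CREST peaks were on 16 of them, with 3 to 15 each, and 11 carried both. Scaffold number and known extent ran in opposite order over the 346 scaffolds (Spearman's rho -0.96, across scaffolds and not replicates), while the 56 numbers from 1 to 100 without a peak of either list have no known extent. Whether scaffolds were left out of a list as a whole is not given in the sources used here, so a count of 0 on a scaffold need not mean that no peak was called there.

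**Figure D4:**
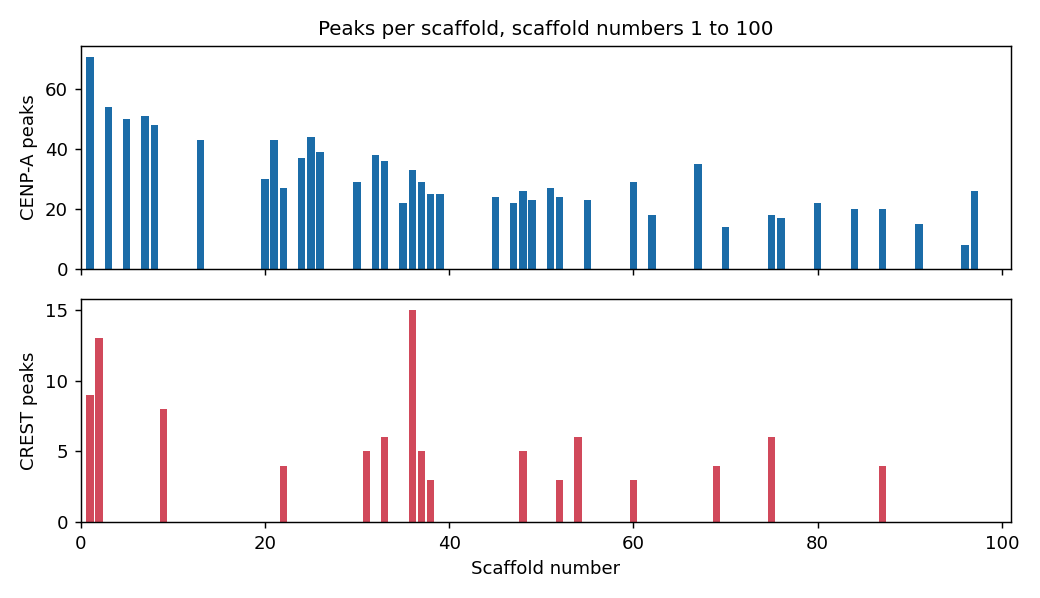
Number of CENP-A peaks (upper panel) and CREST peaks (lower panel) on each scaffold, for scaffold numbers 1 to 100. CENP-A peaks appear on 39 of the 100 numbers, with 8 to 71 peaks where there are any, and CREST peaks on 16, with 3 to 15.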

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

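With 1 library per antibody no replicate could be left out, and the unknown read depth limits what the absence of a peak shows. The wider 50% of each list, the changed splits by extent, the limit to scaffolds with peaks of both lists, the other placements and the other weights of width classes were chosen after the data had been seen. Covered and shared bases, the 212 scaffolds with both antibodies, and the number and length of domains stayed within 1.5 times under both width limits. Requiring an overlap of 50% of the shorter peak, or allowing 1 kb between peaks, left the shares of overlapping peaks inside their intervals. Peaks of at least 500 bp numbered 1229 for CENP-A, with median widths of 1031 bp (CENP-A) and 1639 bp (CREST). Among them 35.0% of CENP-A and 80.1% of CREST peaks overlapped, 5.95% of CENP-A peaks on scaffolds of at least 1 Mb did so, and 35.6% of CENP-A and 77.8% of CREST neighbours lay within 10 kb. The wider 50% of each list held 1206 CENP-A and 379 CREST peaks with medians of 1047 bp and 2369 bp. Of these, 27.9% of CENP-A and 91.8% of CREST peaks overlapped, 54.4% of CENP-A peaks on scaffolds under 1 Mb did so, and 35.8% and 88.7% of neighbours lay within 10 kb. Split at 100 kb, 70.5% of CENP-A peaks on the shorter and 6.71% on the longer scaffolds overlapped a CREST peak, and split at 10 Mb, 43.0% and 1.83%. On scaffolds with peaks of both lists only, 49.0% of CENP-A and 82.5% of CREST peaks overlapped, with 83.6% of CENP-A peaks on scaffolds under 1 Mb and 11.7% on longer ones. The direction between short and long scaffolds was kept under all 3 of these settings. A neighbour distance of 1 kb gave 0% for both lists, since the lists hold no smaller gap, with 520 domains of 1467462 bp in all. A distance of 100 kb gave 37.3% of CENP-A and 79.1% of CREST neighbours and domains of 5834330 bp, so the summed length of the domains is set by the joining distance. Random placement gave a median overlap of 13.0% of CENP-A and 42.9% of CREST peaks. With scaffolds taken as 2 times their known extent it gave 8.50% and 27.8%, and over all known extents end to end 0.166% and 0.528%, all below the observed shares. The random difference between short and long scaffolds in the CENP-A share went from 42.8 to 28.0 percentage points with the scaffolds taken as 2 times as long, and from 27.0 to 16.3 points at equal width. With the 5 width classes weighted equally, by short- or by long-scaffold peaks, the gap at equal width corrected for random overlap was 33.3, 28.4 and 35.4 points, and only the second left the interval of the 38.1 points. Not run, for want of the values they need, were the limits on q and fold enrichment, the comparison of fold enrichment, the placement on true scaffold lengths, and the annotation, sequence and gene comparisons.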

Other observations

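On scaffolds with a known extent of at least 1 Mb, many of the regions marked by both antibodies lay at the far end. Of the 62 CENP-A peaks there that overlapped a CREST peak, 43 (69.4%) lay in the last 10% of the known extent and 4 in the first 10%. They came from 16 of the 30 such scaffolds, with 8 on scaf00036 and 5 each on scaf00255 and scaf00342. Of the 1619 CENP-A peaks without a CREST peak, 13.4% lay in the last 10%. Of the CREST peaks, 74 of 188 lay in the last 10% and 18 in the first 10%.

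The tests of the far end, of evenness over all long scaffolds and of sensitivity with packing taken into account, the random gaps and other weights set beside the width tests, were chosen only after the patterns had been seen. The other tests below were written down before their results were known.

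The known extent ends at the last peak, which need not be the end of the scaffold, so some peaks lie at the far end by construction, and the draws of domains at random within each scaffold keep this. Of the 45 domains that held both antibodies, 23 lay in the last 10%, against a median of 11 and at most 19 in the draws (19 of 41 against a median of 10 and at most 19 without scaf00036), and 5 in the first 10%, against a median of 5. The domain that ends the known extent held both antibodies 15 times, against a median of 5, a central 95% of 2 to 9 and at most 13 (14 against at most 12 without scaf00036), which argues against construction as the whole cause. For the other domains the pattern and its construction cannot be told apart: 8 of 30 lay in the last 10% against a median of 4, a central 95% of 2 to 7 and at most 11, with 3 of the 8 on scaf00036. Assembly breaks or collapsed repeats at centromeres stay open, true scaffold lengths were not used, and no biological explanation was tested.

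Short and long scaffolds differed by 61.8 percentage points in how often CENP-A peaks had a CREST partner. Packing is argued against as the whole cause, since 65.5% overlapped on short scaffolds against at most 47.6% at random, but random placements gave gaps of 42.8 points, or 28.0 with scaffolds taken as 2 times as long, and in proportion to chance the excess was greater on long scaffolds (3.69% against at most 0.297%). A CREST list that finds only the wider peaks was first tested by the gap at equal width, 42.9 points (35.6 to 49.97 over 1000 resamplings of scaffolds) with each class weighted by the product of its short and long counts over their sum, but the limit of 10 points set for it was too low, since packing gave 27.0 points so weighted, and with weights by short-scaffold peaks the gap of 37.0 points lay below the random 42.7. Corrected for random overlap, on scaffolds with peaks of both lists, the gap was 38.1 points (28.8 to 46.2), or 28.4 (19.2 to 36.5) with weights by short-scaffold peaks. Keeping only scaffolds with a CREST peak selects by the outcome, since a short scaffold with few CENP-A peaks may be kept only because 1 has a partner. The share rose to 83.6% on short and 11.7% on long scaffolds, and the correction does not remove this selection. The corrected gap therefore cannot decide whether width alone or missing scaffolds are the whole cause. By width it was 25.4 points (6.92 to 43.8) under 350 bp and 8.41 points (-6.36 to 20.1, 16 long-scaffold peaks) at 2000 bp or more. Both lower bounds lay under 10 points, and those of the classes between lay above. Peak width, scaffolds missing from a list, peak strength, collapsed repeats that raise both lists, and pieces of centromeres on short scaffolds stay open.

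The CENP-A peaks without a CREST partner on long scaffolds were spread as evenly as random placements along the scaffolds that carry them. Over 943 whole windows of 1 Mb, which held 1489 of these 1619 peaks, the variance-to-mean ratio was 0.958, inside the central 95% of random placements (0.921 to 1.09), and 187 windows were empty against a random median of 184. Spill-over around regions marked by both antibodies was tested by distance: 1.48% (Wilson interval 0.998 to 2.20%) lay within 100 kb of one. Only 40 of the 1619 lay within 100 kb of any CREST peak. Of the 1619, 1151 were on scaffolds with no CREST peak listed, where no such region could be near. The share on scaffolds with peaks of both lists alone was not computed. Those scaffolds held 530 CENP-A peaks, 62 of them with a CREST peak, and the 40 were among the others. Only for these scaffolds do the values argue against spill-over as the source of most such peaks. An even background over all long scaffolds was tested on 40 stretches of at least 1 Mb from a scaffold start to its last CREST peak. Of these, 12 held no such CENP-A peak, where the same peaks spread evenly over these stretches left a median of 1 and at most 6 empty. On 11 of the 40 scaffolds no CENP-A peak was listed at all. The test therefore argues against an even background only if no scaffold was left out of the list as a whole, which is not known. A possible explanation is background calls on scaffolds that were kept or left out as a whole, which no source used here describes, and no biological explanation was tested.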
